A study of Homo sapiens with 8 samples.

How the data were processed

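LN229 is an established human glioblastoma cell line. Stable derivatives of it, which carried 1 of the fluorescent proteins ZsGreen and mCherry, were grown as tumour spheroids in low-attachment plates. Per the labels' protocols, 96 spheroids were pooled, dissociated with Accutase and sorted by fluorescence, and poly(A) RNA from 100 ng of total RNA was made into directional libraries and read for 50 cycles, single-end, on an Illumina HiSeq instrument. The labels name each library by a sorted line (GV, RV, GY or RY) and by the pair of lines in its spheroid (GVRV, GYRY, GYRV or GVRY). They do not spell out the letters. From the title of the series Y is read here as raised YAP and V as the control vector, and G and R as the green and the red line. The YAP1 level reported first checks the Y and V labels.

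The deposited values are on a log2 scale. Per the file headers, the authors normalized the values and kept genes for which at least 1 of the 8 libraries had a raw value between 10.0 and 104513.617, in a RefSeq gene model; per the submitters' processing notes the genome build was GRCh38. The aligner, the counter, their versions, their use of strand and the normalization method are not given in the sources used here. In the deposited table each gene's median over the 8 libraries was 0, so the log2 values are relative and the absolute level of a gene is not kept. Of 16865 genes, 3214 had several libraries at a shared lowest value, a floor. A further deposited column, a plain number from 1 to 8, gives in how many libraries the gene passed the authors' lower and upper limits. Above the floor, 74.6 to 77.3% of the low values of a library were whole multiples of 1 step to within 0.1 of a step. That share was too low to recover read counts, so no count test was run. The step sizes put the relative depths of the libraries between 1 and 1.35; the absolute depth is unknown.

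The tests were run with limma 3.58.1 in R 4.3.3 on the deposited log2 values, without a further pseudocount. The 8 libraries were fitted together as 4 groups of 2 with the colour of the line as a further term, which left 3 residual degrees of freedom. Each group held 1 G and 1 R library. Colour, not a replicate number, pairs the same stable lines between the 2 V groups and between the 2 Y groups. Between Y and V it pairs different stable lines that share a colour. The pairing comes from the labels. Genes that passed the authors' limits in at least 2 libraries were tested (15393 genes). The plan had been a variance trend on mean expression, which needs a level that the table does not hold, and a trend on the number of libraries passed could not be fitted. In its place, for the tests of single genes, the empirical Bayes prior was estimated separately for genes that passed in 8 libraries (12272 genes), in 5 to 7 (1437) and in 2 to 4 (1684). This was settled before any count of calls was seen. P-values were adjusted by the Benjamini-Hochberg method and genes under 0.05 were called. The contrasts, the 25 gene lists and the rule for naming genes were fixed before the data were examined.

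Lists were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, over 24 lists; no mitochondrially encoded gene of the remaining list was in the table. Of 576 distinct list genes, 507 were matched by symbol and 26 by gene ID, and 43 were not matched. Markers of other cells formed 3 of the lists (astrocyte, oligodendrocyte and neuron; immune; endothelial and epithelial). By the rule, YAP1 is named in each contrast, and up to 10 called genes per direction with the same sign in G and R lines. Where no gene was called, the 10 genes with the smallest p are named without a verb of change, and for a list without a called member its 2 members with the smallest p. Further genes with small p in the comparison of Y with V lines, and list members past the threshold adjusted over the list alone, were chosen after their values were seen. Gene coordinates are those of RefSeq on GRCh38. Error terms are standard errors (SE) from the fit.

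The procedure was tested on simulated data with the residual spread of the real genes and 200 changed genes among 15393. For 4 against 4 libraries it recovered 46.0% of genes changed by 1 on the log2 scale, 68.0% of those changed by 2 and 94.0% of those changed by 4.2. For V cells beside Y against V cells beside V, 2 against 2 libraries, it recovered 6.0%, 52.0% and 80.0%. With no changed gene it called 0 in either design. The simulated runs with changes held 6 and 5 false calls among 151 and 115 calls. So many calls ease the adjusted threshold beyond that of the real data, where few or no genes were called. The simulated noise was normal and independent, with no floor and no difference between pools. The shares recovered may therefore be higher than in the real data. The labels do not say that libraries of 1 group came from separate cultures, and the series describes its 8 samples as unduplicated. The p-values therefore measure only the spread left between these samples after the colour term, and it may be technical. A difference between G and R lines common to all groups is taken out, while one that varies between groups is included. The 4 Y libraries came from 2 stable lines, as did the 4 V libraries. The 8 libraries came from 4 pools of spheroids. Both libraries of V beside V came from the GVRV pool and both of Y beside Y from the GYRY pool, while each mixed pool gave 1 Y and 1 V library. Each unmixed group is thus 1 pool, and the fits treat libraries of 1 pool as independent. The effects of a neighbour, of mixing and of Y against V between unmixed spheroids therefore include any difference between pools. The comparison of Y with V lines averages the mixed and the unmixed spheroids, so it includes in part any difference between the 2 unmixed pools. Alternatives tried were quantile normalization, other filters, other models and priors, the means of the 4 pools, a correlation between libraries of 1 pool, a minimum fold of 1.5, leaving out each library in turn, and leaving out the 2 libraries of widest spread. Quantile normalization acted on the centred values and so gave them the same spread in each library. It can move most the genes far from their median, YAP1 among them, and is not a test of library scaling alone. Count tests and a change of pseudocount were not run, since the values are logarithms without counts.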

Results

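Gene expression was measured by RNA sequencing in LN229 glioblastoma cells sorted from tumour spheroids that held a pair of differently coloured lines. The 8 libraries formed 4 groups of 2: V cells beside V cells, V cells beside Y cells, Y cells beside V cells, and Y cells beside Y cells, each with 1 green (G) and 1 red (R) line. The unmixed spheroids were GVRV and GYRY, and the mixed ones were GYRV and GVRY. Each unmixed group was a single pool of spheroids, from which both of its libraries came, so its 2 libraries do not measure the spread between pools. The title of the series places the study in cell competition, in which cells of 1 kind are lost beside cells of another. The comparisons therefore ask how Y and V cells differ, and how each is altered by its neighbour. Values are log2 levels relative to the gene's median over the 8 libraries, and the relative depth of the libraries ranged from 1 to 1.35.

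YAP1, the transcriptional co-activator restrained by the Hippo pathway (gene ID 10413; GRCh38 chromosome 11, 102110447 to 102233424, protein-coding), separated Y from V libraries. Its centred log2 level lay between 1.91 and 2.10 in the 4 Y libraries and between -2.59 and -1.91 in the 4 V libraries. YAP1 was higher in Y than in V lines by 4.25 (SE 0.11, 95% confidence interval 3.96 to 4.53), a 19.0-fold difference, with an adjusted p of 0.00182 by limma. It was 23.8-fold higher between unmixed spheroids (log2 4.57, SE 0.16, adjusted p 0.00765) and 15.1-fold higher within mixed spheroids (log2 3.92, SE 0.16, adjusted p 0.0172). The G and R lines gave nearly equal differences, 4.19 and 4.30. The call rested on few degrees of freedom: with 1 library left out the difference stayed between 4.18 and 4.31 while the adjusted p ran from 0.044 to 0.0587, above the threshold without the G line of V beside V (0.0519) or any of the 4 Y libraries (0.0542 to 0.0587). The calls within mixed and between unmixed spheroids were lost without any 1 of the 8 libraries (adjusted p 0.171 to 0.516 and 0.0805 to 0.317). The Y against V call missed the threshold under quantile normalization (4.64, adjusted p 0.143) and in the mixed spheroids alone with the spheroid as block (3.92, adjusted p 0.669).

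**Figure D1:**
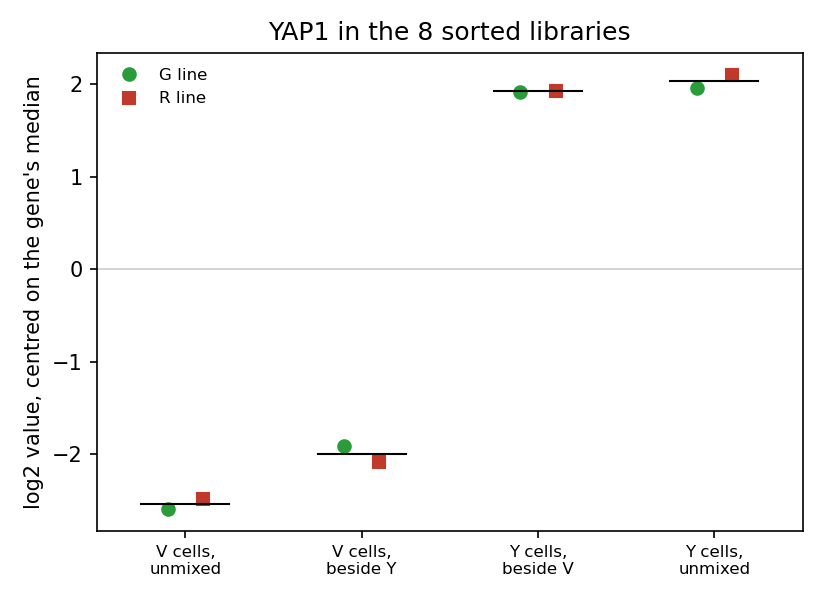
YAP1 in each of the 8 libraries, as the log2 value centred on the gene's median (vertical axis), by group (horizontal axis). Circles are G lines, squares R lines and bars the means of the 2 libraries; the Y libraries lie between 1.91 and 2.10 and the V libraries between -2.59 and -1.91.

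Beyond YAP1, no gene passed the threshold between Y and V lines: 1 of 15393 genes was called, and 1356 had an unadjusted p under 0.05, against 770 for chance. The genes with the smallest p after YAP1 passed the authors' limits in 8 of 8 libraries. Lower values in Y lines were found for ITIH5 (log2 difference -2.45, SE 0.15, adjusted p 0.0617) and ITIH6 (-2.42, SE 0.21, adjusted p 0.134), inter-alpha-trypsin inhibitor heavy chains, and for the hyaluronan link protein gene HAPLN1 (-2.76, SE 0.20, adjusted p 0.0776). The matrix genes COL9A1 (-1.39) and ABI3BP (-2.06), the neuroendocrine granin SCG2 (-1.40), the lipocalin APOD (-1.33), the growth factor PTN (-0.93), the protease inhibitor A2M (-1.43) and the actin-filament adaptor AFAP1L2 (-1.75, SE 0.12, adjusted p 0.0678) also had lower values. Higher values in Y lines were found for the small secreted protein gene FDCSP (1.98, SE 0.13, adjusted p 0.0617), the cytokine genes IL1B (1.42, SE 0.12, adjusted p 0.109) and IL15 (1.64; means of 1.47 in Y beside V and -1.59 in V beside Y, against 0.21 in Y beside Y and 0.00 in V beside V), the cytokine receptor IL31RA (1.49), the adhesion molecules L1CAM (1.05) and PCDH1 (1.20), the class II antigen gene HLA-DRA (1.32) and the AP-1 subunit FOSL1 (0.79). These genes were named after their values were seen, and each had the same sign in G and R lines. With no colour term limma called 6 genes, YAP1, IL1B, FDCSP, HAPLN1, AFAP1L2 and ITIH6, and with the genes that passed in all 8 libraries it called 3, YAP1, FDCSP and ITIH5.

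**Figure D2:**
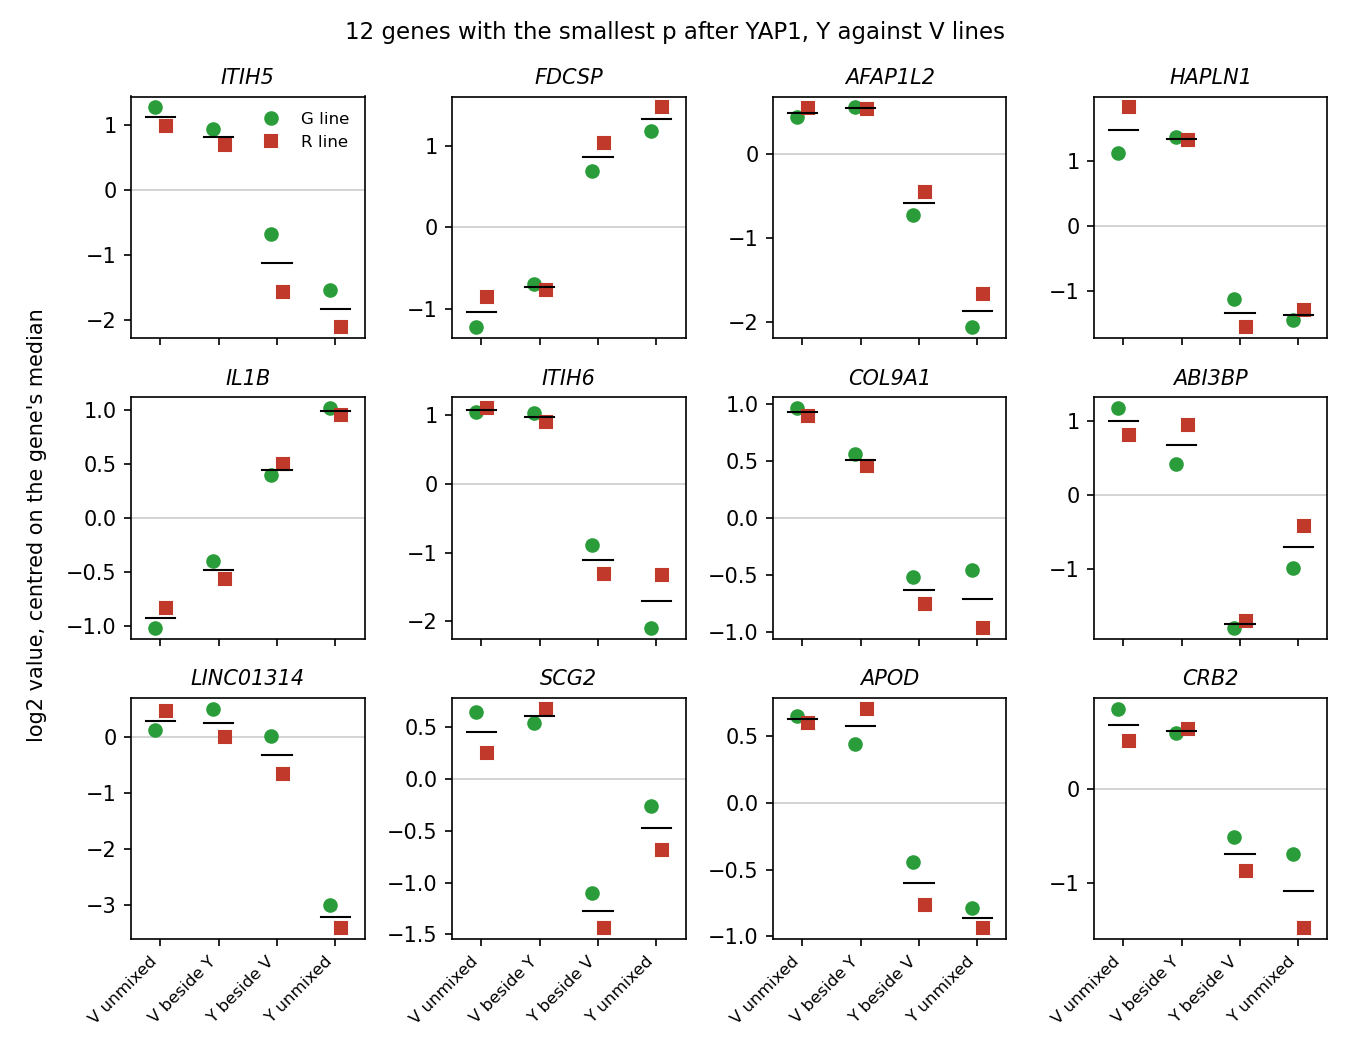
The 12 genes with the smallest p after YAP1 between Y and V lines, each as centred log2 values (vertical axes) by group (horizontal axes). Circles are G lines, squares R lines and bars the means of the 2 libraries; ITIH5 is lower in Y lines by 2.45 and FDCSP higher by 1.98, and none of the 12 passed the adjusted threshold.

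The 21 measured YAP/TAZ-TEAD target genes did not pass as a list between Y and V lines, with 14 higher and 7 lower in Y (median 0.14, adjusted p = 0.355 by camera). Their median was above those of the Hippo (0.12), actin (0.10) and NF-kB (0.08) lists, which passed, and below that of the cholesterol list (0.15). A shared shift of the target genes is therefore not excluded. Of the 21 target genes 0 were called over all genes by limma and 2 passed when adjusted over the list alone, both lower in Y. CTGF, a matricellular protein gene and classical YAP target, was the one of smaller p (-1.10, SE 0.18, p 0.0322 adjusted over the list alone). CYR61, its close relative in the same protein family, had a value of 0.78 (SE 0.23) and did not pass. Hippo pathway components were shifted up as a list (17 of 26 positive, median 0.12, adjusted p = 0.0198 by camera; adjusted p = 0.668 with an estimated correlation). The list includes YAP1, the 1 member called over all genes; adjusted over the list alone 3 passed, with WWC1 at 0.98 (SE 0.15) and the YAP partner TEAD4 at 0.67 (SE 0.12). Without YAP1 the list had an adjusted p of 0.0781.

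Actin cytoskeleton and adhesion genes were shifted up in Y lines, with 19 of 26 positive and a median of 0.10 (adjusted p = 0.00462 by camera; adjusted p = 0.785 with an estimated correlation). TPM1, a tropomyosin (0.68, SE 0.10), and ITGA3, an integrin subunit (0.62, SE 0.11), passed when adjusted over the list alone, and 0 members were called over all genes by limma. NF-kB and cytokine genes were shifted up with 14 of 21 positive (median 0.08, adjusted p = 0.0297; adjusted p = 0.668 with an estimated correlation); IL1B and the chemokine CXCL1 (0.73, SE 0.12) passed over the list alone. Cholesterol synthesis genes were shifted up with 20 of 24 positive (median 0.15, adjusted p = 0.0297; adjusted p = 0.785 with an estimated correlation), with values of 0.61 for HMGCS1 and -0.65 for HSD17B7, the 2 members of smallest p. Replication-dependent histone genes were shifted down, with 14 of 15 negative (median -0.74, adjusted p = 0.0198; adjusted p = 0.87 with an estimated correlation); only 4 of the 15 passed the authors' limit in 8 libraries and 7 had a library at the floor. HIST1H1B had -3.78 (SE 1.18) and HIST2H2BE -0.41 (SE 0.19). Camera used 1 prior for all genes, which gives genes at the floor the spread of all genes. The mean of the list did not separate Y from V among the G libraries (0.47 and -0.39 for GY, -0.63 and 0.13 for GV). It was highest in the R line of V beside V (0.91) and lowest in the R line of Y beside V (-2.30). These 2 libraries also had the widest spread over genes that passed in all libraries (SD 0.45 and 0.426, against 0.327 to 0.396 in the other 6) and the highest numbers of genes at the floor (2221 and 2220, against 1480 to 2033). Without both, a choice made after the values were seen, 1 residual degree of freedom was left, the histone median was -0.197 (adjusted p 0.666) and none of the 5 lists passed by camera (0.128 to 0.176 for the other 4). By fry, which does not set a list against other genes, 6 lists passed. Actin, Hippo, NF-kB and mesenchymal and TGF-beta response genes were up (adjusted p 0.0415, 0.0311, 0.0311 and 0.0311), and interferon response genes and astrocyte, oligodendrocyte and neuron markers down (0.0311 and 0.0378); cholesterol and histone genes did not pass (0.346 and 0.476). Under quantile normalization camera kept actin genes alone of the 5; Hippo and cholesterol genes each had 0.0593, NF-kB genes 0.0803 and histone genes 0.0713 (median -0.376). With genes that passed in all 8 libraries, NF-kB genes (0.0724) and histone genes (4 members, median -0.241, adjusted p 0.35) were lost. With 1 library left out, camera passed 1 to 5 lists, which held 1 to 4 of these 5. NF-kB genes were lost without any 1 of the 8 libraries (adjusted p 0.0589 to 0.152, medians 0.06 to 0.161), and actin genes without the R line of Y beside V (0.0545). Hippo genes were lost without the G line of V beside V (0.166), the R line of Y beside Y (0.141), the G line of Y beside V (0.0696) or the R line of V beside Y (0.234), with medians of 0.064 to 0.157 over the 8. Cholesterol genes were lost without the G line of V beside V (0.385), either line of Y beside Y (G 0.055, R 0.116), the R line of V beside Y (0.383) or the R line of Y beside V (0.195), with medians of 0.058 to 0.238. Histone genes were lost without any 1 of the 4 R libraries: V beside V (median -0.247, adjusted p 0.266), Y beside V (-0.26, 0.347), Y beside Y (-0.625, 0.151) and V beside Y (-0.48, 0.241). Without 1 of the G libraries their median was -1.892 (V beside V), -1.661 (Y beside V), -1.165 (V beside Y) or -1.084 (Y beside Y).

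**Figure D3:**
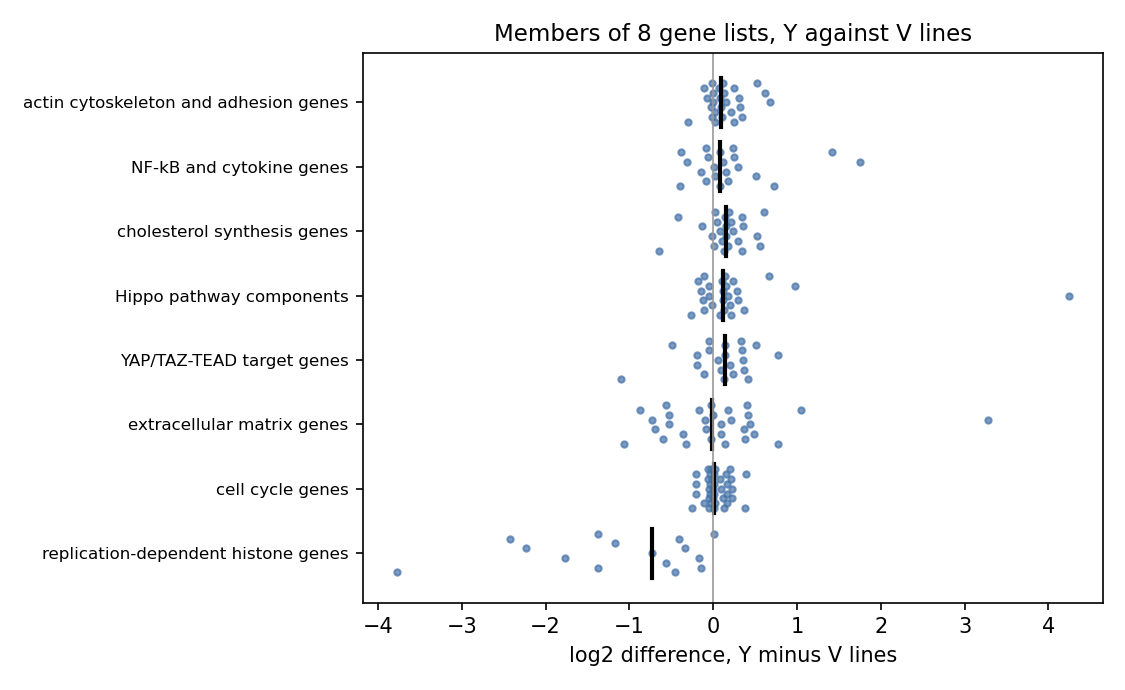
Log2 difference between Y and V lines (horizontal axis) of the measured members of 8 gene lists (vertical axis). Each point is a gene and each black bar the median of its list; the actin and adhesion list has a median of 0.10, the YAP/TAZ-TEAD target list of 0.14 and the histone list of -0.74.

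Extracellular matrix genes went both ways, with 14 of 30 positive (median -0.01, mean 0.05, adjusted p = 0.875 by camera) and 0 called over all genes by limma. Adjusted over the list alone 8 passed. COL5A1 (0.77, SE 0.11), TGFBI (0.49, SE 0.12) and COL1A2 (3.28, SE 1.14, with 3 libraries at the floor) were higher in Y lines. BGN, the proteoglycan biglycan (-1.06, SE 0.16), COL12A1 (-0.69), COL6A1 (-0.60), COL6A2 (-0.53) and FN1, fibronectin (-0.52, SE 0.12), were lower. Among immediate early and dissociation response genes (adjusted p = 0.705), FOSL1 (0.79, SE 0.11), NR4A1 (-0.64, SE 0.11) and EGR2 (-0.51, SE 0.11) passed over the list alone. Of the mesenchymal and TGF-beta response genes (adjusted p = 0.129 by camera and 0.0311 by fry), TPM1 was higher and SNAI1, an epithelial-mesenchymal transition factor, lower (-0.64, SE 0.12), adjusted over the list alone. Cell cycle genes had a median of 0.01 (21 of 38 positive, adjusted p = 0.355), and cell competition genes a median of -0.06 (5 of 15 positive, adjusted p = 0.795), with 0 members passing over the list alone in either by limma and CCNE1 at 0.38 and AZGP1 at -0.65 as their members of smallest p. The cell cycle median varied with the library left out. It was 0.145 without the G line of Y beside V and 0.085 without the G line of V beside Y.

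Of the markers of other cells between Y and V lines, astrocyte, oligodendrocyte and neuron markers had an adjusted p of 0.0957 by camera (4 of 11 positive, median -0.18), but passed, downward, by fry (0.0378) and by camera with the 8 members that passed in all libraries (median -0.253, adjusted p 0.0461), with the neuronal microtubule gene MAP2 lower over the list alone (-1.09, SE 0.22). Immune cell markers had an adjusted p of 0.705 by camera, with HLA-DRA higher over the list alone, and endothelial and epithelial markers had 0.59, with KDR lower over the list alone (-3.91, SE 1.18, with 4 libraries at the floor). Interferon response genes had 0.861 by camera. The 9 lists not named so far between Y and V lines had adjusted p-values by camera from 0.0696, for glycolysis genes, to 0.986, for neural stem and glioma stem cell genes.

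Whether V cells were altered by Y neighbours was asked by setting V cells of mixed spheroids against V cells of unmixed ones. YAP1 was 0.54 higher in V cells beside Y (SE 0.16), by 0.68 in the G and 0.41 in the R line, and this did not pass (adjusted p 0.856); under quantile normalization the difference was -0.09. The 10 genes of smallest p had equal adjusted values of 0.856. Positive values were found for the sorting nexin SNX16 (1.40, SE 0.18), EVI5L (1.34, SE 0.19), the threonine aspartase TASP1 (0.99, SE 0.14), the prolactin receptor PRLR (1.04, SE 0.16) and TSIX (7.24, SE 1.82). Negative values were found for TMEM171 (-1.57, SE 0.18), SERTAD3 (-1.32, SE 0.18), STBD1 (-1.44, SE 0.21), the read-through gene TNFSF12-TNFSF13 (-1.46, SE 0.22) and the protocadherin PCDHGA6 (-2.22, SE 0.33), one of a cluster of near-identical genes whose reads are uncertain. limma called 0 of 15393 genes, with 859 at an unadjusted p under 0.05 against 770 for chance, and no list passed. Unfolded protein and ATF4 response genes had a median of 0.18 (18 of 24 positive, adjusted p = 0.187 by camera). Their median was 0.431 without the G line of V beside Y, which left 1 library in that group. There hypoxia genes had a median of 0.39, cell cycle genes -0.235 and cholesterol synthesis genes -0.267. The median SE was 0.22 for genes that passed in all libraries, and in simulated data of this design 6.0% of genes changed by 1 on the log2 scale were recovered.

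For Y cells beside V against Y cells beside Y, YAP1 differed by -0.11 (SE 0.16, adjusted p 0.95). Each of the 10 genes of smallest p had a positive value. The glycogen phosphatase gene EPM2A (2.21, SE 0.20), LINC01314 (2.89, SE 0.28) and TMEM110-MUSTN1 (1.73, SE 0.17) had an adjusted p of 0.471, as did TSIX (8.78, SE 1.82). CMTM8 (1.39, SE 0.15), PCDHB19P (1.96, SE 0.22), the cell cycle regulator SPDYA (2.15, SE 0.26), the mitochondrial pyruvate carrier MPC1 (1.53, SE 0.19), AFAP1L2 (1.28, SE 0.17) and the antisense RNA TRAF3IP2-AS1 (2.00, SE 0.27) followed with adjusted p-values from 0.484 to 0.776. AFAP1L2 and LINC01314 had low means in the Y beside Y libraries (-1.87 and -3.21, against -0.58 and -0.33 in Y beside V), which this comparison shares with that of Y and V lines. Y beside Y also had the lowest group mean for EPM2A (-0.48), TMEM110-MUSTN1 (-1.19), CMTM8 (-1.11), PCDHB19P (-1.96), SPDYA (-1.54), MPC1 (-1.25) and TRAF3IP2-AS1 (-1.26), but not for TSIX. Both libraries of Y beside Y came from 1 pool, so a difference of that pool cannot be told apart from an effect of V neighbours. limma called 0 genes, with 909 at an unadjusted p under 0.05, and no list passed.

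Between mixed and unmixed spheroids over both kinds of cell, limma called 1 gene and 836 had an unadjusted p under 0.05. TSIX, the antisense RNA of the X-inactivation centre (gene ID 9383, chromosome X), was higher in mixed spheroids by 8.01 (SE 1.29, adjusted p 0.0188). It passed the authors' limit in 5 libraries, 2 lay at the floor, and 1 of the 4 mixed libraries lay within the range of the unmixed ones. It overlaps a gene on the other strand, and the use of strand in counting is not known, so its identity is uncertain. The call was lost without the colour term (adjusted p 0.523) and without any of 6 libraries (adjusted p from 0.0549 to 0.997), which were both V libraries of unmixed spheroids, the G line of Y beside Y, both Y libraries of mixed spheroids and the R line of V beside Y. YAP1 differed by 0.22 (SE 0.11, adjusted p 0.908), and no list passed.

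The neighbour effect was then compared between Y and V cells. limma called 0 genes for this difference, with 939 at an unadjusted p under 0.05. The 10 genes of smallest p, with an adjusted p of 0.802, had positive values for the effect in Y cells minus that in V cells: EPM2A (2.57, SE 0.28), CMTM8 (1.88), TMEM110-MUSTN1 (2.16), PCDHGA6 (4.05), TMEM171 (2.13), TRAF3IP2-AS1 (3.11), LINC01314 (2.92), the long noncoding RNA JPX (2.13), STBD1 (2.18) and IL15 (2.85). A positive value does not say in which cells the effect was larger. PCDHGA6, for example, had means of 1.97 in V beside V and -0.25 in V beside Y. Its means were -1.24 in Y beside Y and 0.59 in Y beside V. Cholesterol synthesis genes had the smallest list p (21 of 24 positive, median 0.24, adjusted p = 0.0874; adjusted p = 0.934 with an estimated correlation).

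Within mixed spheroids, where Y and V cells came from the same spheroids, limma called YAP1 alone, with 1122 genes at an unadjusted p under 0.05. Actin cytoskeleton and adhesion genes were shifted up in Y cells (22 of 26 positive, median 0.18) and so were cholesterol synthesis genes (22 of 24 positive, median 0.30), both with adjusted p = 0.00095 by camera and adjusted p = 0.819 with an estimated correlation. Histone genes were shifted down (13 of 15 negative, median -1.50, adjusted p = 0.0183; adjusted p = 0.819 with an estimated correlation). None of the 3 passed by fry. The histone list was also lost under quantile normalization (median -1.182, adjusted p 0.123) and with its 4 members that passed in all 8 libraries (median -0.169, adjusted p 0.789). Without the R line of Y beside V, or the R line of V beside Y, the adjusted p of the cholesterol list became 0.146 and 0.569, that of the actin list 0.146 and 0.0567, and that of the histone list 0.728 (median -0.392) and 0.569 (median -0.817). The cholesterol median was then 0.158 and 0.152. Without the G line of Y beside V the histone median was -3.561, and without the G line of V beside Y it was -2.278 and the cholesterol median 0.469. Between unmixed spheroids limma again called YAP1 alone, with 1258 genes at an unadjusted p under 0.05. No list passed by camera there, the smallest adjusted p being 0.0808 for the Hippo list (18 of 26 positive, median 0.12) and for mesenchymal and TGF-beta response genes (18 of 23 positive, median 0.18).

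The G and R lines, sorted by different fluorescent markers, served as a control comparison. limma called 0 genes, with 864 at an unadjusted p under 0.05, and YAP1 differed by 0.02 (SE 0.11). The 10 genes of smallest p, with an adjusted p of 0.889, were RDH13 (-0.87), MYPN (-5.52), STEAP2 (-0.81), TMEM110-MUSTN1 (-0.87), TASP1 (-0.68) and PAXIP1-AS2 (-1.39), lower in R, and DGKB (5.52), KCNRG (1.40), ZFP69 (1.29) and TBC1D2 (1.34), higher in R; MYPN and DGKB each had 4 libraries at the floor. Cytosolic ribosomal protein genes were shifted up in R lines (27 of 30 positive, median 0.11, adjusted p = 0.0013 by camera; adjusted p = 0.935 with an estimated correlation). Without any 1 of the 4 V libraries the list no longer passed. Its median was 0.067 without either V beside V library and 0.085 without either V beside Y library. Without either Y beside Y library it was 0.121, and without either Y beside V library 0.148. Other coding genes in their range of transcript lengths, 7216 of 11306 genes, had a median of 0.005 (bootstrap interval -0.001 to 0.01), and 536 genes matched more closely in length, a comparison chosen after the values were seen, had 0.067 (0.048 to 0.082).

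Across genes, the differences found in the G lines were only weakly related to those in the R lines. For Y against V the Pearson correlation across 15393 genes was 0.068 within mixed and 0.022 between unmixed spheroids. For the effect of a neighbour it was -0.007 in V cells and 0.024 in Y cells; the Spearman rank correlations were 0.067, 0.11, 0.041 and 0.023 in the same order. Among the 12272 genes that passed in all 8 libraries the Pearson values were 0.074, 0.153, 0.039 and 0.029 in that order, so the order of the first 2 depends on the filter. Genes are not independent replicates, so no p is given. The correlations also differ in how pools enter them. Between unmixed spheroids both colours compare the same 2 pools, so a difference between pools raises the correlation. Within mixed spheroids the pools enter G and R with opposite signs, which lowers it. For each effect of a neighbour both colours share the unmixed pool, which raises it. All 4 Y libraries lay above all 4 V libraries for 431 genes and below for 444, 5.68% of genes against 2.86% by chance.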

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

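The weighing here was written after the YAP1 values were known, but before the test of the other genes was run. By a test of YAP1 alone, though not after adjustment over all genes, its neighbour effect differed between Y and V cells: the effect of mixing in Y cells minus that in V cells was -0.654 (SE 0.22), with an unadjusted p by limma of 0.0305 for this gene, fixed beforehand, and an adjusted p of 0.802 over all genes. Each unmixed group was a single pool, so these p-values do not measure the spread between unmixed pools. A difference between pools is therefore not excluded. In V cells both colours had higher YAP1 beside Y (0.68 and 0.41), and in Y cells both had slightly lower values beside V (-0.05 and -0.17). Under quantile normalization the difference turned to 0.17, and the value in V cells to -0.09. That step forces the centred values of all libraries to 1 distribution, and YAP1 lies far out in it. The turn therefore does not show whether library scaling makes the pattern, which stays undecided. No group holds 4 libraries, so no library was tested as standing apart from its group; the R lines of V beside V and Y beside V had the widest spread (SD 0.45 and 0.426). Without these 2, an alternative chosen after the data were seen, the difference was -0.73.

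A candidate explanation is a small share of Y cells left among the sorted V cells. The YAP1 shift would need 2.68% of Y cells in the G and 1.41% in the R library. Such a share would raise other genes that were higher in Y cells; these were chosen in the opposite colour of the unmixed spheroids (596 and 318 genes), and the share predicted median shifts of 0.059 and 0.029. The observed medians were 0.067 (bootstrap interval 0.012 to 0.127) in G and 0.037 (-0.076 to 0.151) in R. By the rule set beforehand the G library met the prediction and the R library did not decide. The choice of genes and the test share the GVRV pool. Genes low in that pool are chosen and would then shift up without leftover Y cells. The bootstrap draws genes within 1 pair of libraries and holds no spread between libraries or pools. The G result is therefore not support for leftover Y cells. Leftover Y cells and a rise of YAP1 within V cells cannot be told apart here. The choice of genes shares a pool with the test, and the R interval spans both 0 and the predicted shift. An effect of Y neighbours on YAP1 in V cells remains undecided (0.54, adjusted p 0.856 by limma).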

How the results depend on the processing

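The alternatives chosen only after seeing the data were the single and the robust prior, the filter on 4 libraries, the additive fit, line means, pool means, the correlation within a pool, the 6 libraries other than the R lines of V beside V and Y beside V, Y or V as the only term, and all alternatives for lists except fry and the estimated correlation. YAP1 was higher in Y lines under every alternative run, by 4.18 to 4.31 with 1 library left out, 4.64 under quantile normalization (adjusted p 0.143) and 3.92 in mixed spheroids alone with the spheroid as block (adjusted p 0.669); it was 4.266 in those 6 libraries (adjusted p 0.519); over the alternatives its adjusted p ran from 2.95e-05 to 0.669. With libraries left out, or in 2 groups alone, fewer degrees of freedom remained. Averaged to 2 Y and 2 V lines, the adjusted p was 0.0209.

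Against 1 gene called between Y and V lines, limma called 3 with genes passed in all 8 libraries, 6 with no replicate block (no colour term, 3 higher and 3 lower), 0 in mixed spheroids alone, 2 in the additive fit, 9 with Y or V as the only term, 21 (9 higher, 12 lower) when that was joined with genes passed in all 8 libraries, 11 with a single prior (5 higher, 6 lower), and 0 to 1 with a library left out. Under quantile normalization the 1 gene was ITIH5, lower in Y, in place of YAP1. The single prior called 12 genes in V cells beside Y, 9 in Y cells beside V, 1 for the difference of these effects, 14 between Y and V within mixed and 9 between unmixed spheroids, and 0 between mixed and unmixed; it gives genes at the floor the spread of all genes. Mixed against unmixed called 0 with genes passed in all 8 libraries and 0 with no replicate block, and 0 to 1 with a library left out. In the 6 libraries, with 1 residual degree of freedom, limma called 0 genes in every comparison (1311 between Y and V lines at an unadjusted p under 0.05), and camera 0 lists between Y and V lines, 0 within mixed spheroids, 1 between R and G lines (cell cycle genes, down) and 1 in V cells beside Y (histone genes, up). Within mixed and between unmixed spheroids the call of YAP1 became 0 under quantile normalization, 0 in the 2 groups compared alone and 0 without any 1 library. The cause was not tested where the number of samples or genes does not give it. No other call changed without the colour block. Neighbour effects and R against G stayed at 0 calls by limma under the other alternatives, a library left out included.

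YAP1 turned sign under quantile normalization in V cells beside Y (-0.085), Y cells beside V (0.082), mixed against unmixed (-0.0015) and the difference of neighbour effects (0.17), and between R and G lines ran from -0.016 to 0.088 with a library left out and was 0.54 under quantile normalization, against 0.02; none of these had passed. CXCL8, at 0.29 between Y and V lines, had -0.12 in mixed spheroids alone. Of 2901 checks of single genes 2827 kept direction and side of the threshold, 31 lost and 33 gained a call and 10 turned.

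Against 5 lists between Y and V lines, camera called 0 with an estimated correlation 1 under quantile normalization (actin genes) and 4 with genes passed in all 8 libraries, 3 of them among the 5, and fry 6, of which 3 were among the 5. With a library left out, 1 to 5 lists were called, 1 to 4 of them among the 5. Against 3 lists within mixed spheroids, 2 were called under quantile normalization and 2 with genes passed in all 8 libraries, without the histone list in both, 0 with an estimated correlation and 0 by fry, and 0 to 6 with a library left out, 0 to 3 of them among the 3. Between unmixed spheroids fry called 1 list. Against 1 list between R and G lines, 0 were called with an estimated correlation and 0 by fry, and 0 to 1 with a library left out. Leaving out a library gave 0 to 4 lists in V cells beside Y, 0 to 1 in Y cells beside V, 0 to 3 between mixed and unmixed, 0 to 2 for the difference of these effects and 0 to 2 between unmixed spheroids. With genes passed in all 8 libraries the correlation between colours was 0.153 for Y against V in unmixed spheroids and 0.039 for V cells beside Y. Where a library was left out, the lone library of its group was assumed to vary like the others. DESeq2, voom, TMM scaling, the pseudocount and the upper range of mean expression were not run, since the table holds no counts and no mean levels; the filter on level was replaced by the number of libraries passed. TSIX was called by limma on pool means (adjusted p 9.93e-07) and with a correlation within pools (0.0107), over a range of 9.93e-07 to 0.997. The pool means left 2 residual degrees of freedom, so their p leaned on the prior spread of genes passed in 5 to 7 libraries. With a single prior for all genes TSIX had an adjusted p of 0.744 by limma. The correlation within pools, -0.192, rests on 4 pools, 2 of them each a whole group, and no count of genes changed with it. Depth is unknown, and genes near the floor limit the histone and TSIX results.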

Other observations

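The tests in this part that were chosen only after the results were seen are the length-matched comparison of ribosomal protein genes, the cell cycle comparison of histone genes and the splits balanced for colour. Interferon response genes had 11 of 26 members positive between Y and V lines and an adjusted p of 0.861 by camera but 0.0311 by fry, downward. The antiviral gene IFIT2 was lower in Y when adjusted over the list alone (-1.10, SE 0.15), while IFIT1 (-1.13) and HERC5 (0.73) did not pass. Glycolysis genes were mostly higher in Y (15 of 19 positive, median 0.10, adjusted p = 0.0696), with SLC16A3, a lactate transporter, at 0.55 (SE 0.13) and ALDOC at -0.44 (SE 0.14). Of 159 genes that differed by over 2-fold between Y and V in both colours of the unmixed spheroids, 64 had the same direction in both colours of the mixed spheroids and 25 the opposite direction in both; among genes that passed in all libraries 29.3% had the same direction in both colours. Of the variance between libraries in those genes, Y against V took 18.3%, mixing 14.0% and colour 14.3%, where chance gives 14.3% to each.

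Other splits of the 8 libraries into 4 and 4 were fitted without further terms. The split into Y and V called 9 genes (YAP1, HAPLN1, FDCSP, ITIH6, APOD, FAM19A2, L1CAM, ITIH5 and COL9A1) and the highest of the other splits 1, so that 1 of 35 splits, the real one, gave as many. That would exclude a chance division only if all 8 libraries were exchangeable. They came from 4 stable lines and 4 pools, so libraries share lines and pools, and chance between lines is not excluded. Of the 18 splits with 2 G and 2 R libraries on each side, the real one called 9 genes without and 7 with a colour term, and the highest other 0 and 1; 18 splits are too few for a share under 0.05. The splits do not separate YAP from other differences between the 2 Y and the 2 V lines. The mixed against unmixed split and the R against G split each called 0 genes (688 and 712 at an unadjusted p under 0.05), which 35 of 35 splits reached, with a highest other of 9; since every split reaches 0, this says nothing of chance. For gene lists by camera at the preset correlation, 6 of 35 splits reached the 5 lists of Y against V, with a highest other of 7. For R against G 2 lists were called, reached by 18 of 35, so chance is not excluded for the lists of Y against V or of R against G. For mixed against unmixed 0 lists were called, which all 35 splits reach whatever the grouping.

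The shift of ribosomal protein genes between R and G lines lay in the V lines: the median difference was 0.25 in V beside V (27 of 30 genes higher in R) and 0.15 in V beside Y (28 of 30), against -0.01 in Y beside V and 0.04 in Y beside Y. It exceeded 0.05 in 2 of the 4 groups, so it was neither in a single library nor in most groups, and the difference between V and Y lines was not tested. Transcript length may contribute. The first test compared other coding genes between 359 and 4498 nt (median 0.005), but that range took in 7216 of 11306 coding genes, too wide to tell; 536 genes matched in length had a median of 0.067 (bootstrap interval 0.048 to 0.082), against 0.107 (0.075 to 0.133) for the ribosomal protein genes. Length and a difference between the lines cannot be told apart, since the interval of the matched genes overlaps that of the ribosomal protein genes.

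The lower histone values of Y lines, which passed as a list only with all 4 R libraries present, were uneven between colours, with a mean over the list of -1.08 and -2.30 in the RY libraries against 0.91 and 0.81 in the RV libraries. The G libraries showed no common direction. There the mean was higher in Y between unmixed spheroids (0.47 for GY, -0.63 for GV) and lower in Y within mixed ones (-0.39 for GY, 0.13 for GV). The cell cycle list had a median of 0.007 (bootstrap interval -0.03 to 0.089), but with 21 members higher and 17 lower over both colours it does not decide whether fewer Y cells were in S phase. Unequal carry-over of RNA without poly(A) tails also remains a candidate explanation: 114 other such RNAs, of which 10 passed in all libraries, had a median of -0.339 (-0.483 to 0.053), an interval that holds both 0 and the value carry-over would need. These explanations cannot be told apart here, and no other biological one was tested.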
